A study of Mus musculus with 6 samples.

How the data were processed

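Gene expression was measured in Beko cells, a mouse T-lineage leukaemia cell line, on 6 Affymetrix arrays hybridised with biotin-labelled total RNA. There was 1 array for each of 6 conditions. Parental cells received the γ-secretase inhibitor DAPT at 10 μM or its vehicle DMSO for 24 h. Cells carrying a DNMAML-ER or a Notch1-ER fusion received hydroxytamoxifen (OHT) at 0.75 μg/mL or its vehicle ethanol for 48 h. The labels and the series' design text disagree on the position of the hydroxyl group of the tamoxifen metabolite, so it is called OHT here. The labels give no replicate, batch or scan date.

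The deposited values are log2 expression values made by the authors with RMA, per the submitters' processing notes, which give no version. RMA corrects the background of each array, sets the probe distributions of all arrays equal and summarises the probes of each probe set. It makes arrays comparable in rank and overall distribution, and it would absorb a change in total RNA per cell. The table holds 22414 probe sets, each named by 1 mouse Ensembl gene ID, and its values run from 1.51 to 14.0 with 0 missing. The array model, the annotation release and the genome build are not given in the sources used here. The medians of the 6 arrays lay between 5.43 (DAPT) and 5.61 (DNMAML-ER with ethanol). The number of arrays limits the precision of every value below.

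The table pairs no ID with a gene symbol. Of the 22414 IDs, 0 matched an Ensembl ID in the gene table supplied as a reference for the GRCm38.p6 assembly, so genes are not named here and no coordinates are given. The preset gene lists (Notch targets, Notch pathway components, metabolism, cell cycle, lineage markers and stress responses), the check of Notch1, Maml1, Esr1 and Carm1 levels, and every part of the naming rule that needs a symbol were therefore not analysed here. Genes are printed by ID for at most 2 in each direction. They are those with the largest value of the smallest of the 3 signed differences, which is the preset rule for genes shared by the 3 pairs.

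Differences were computed with R 4.3.3 as treated minus vehicle on the deposited log2 scale, so a difference of 1 is a 2-fold change. Genes had to reach, on at least 1 of the 6 arrays, the median over all probe sets of the mean level (5.54), which left 12150 genes. With 1 array per group no test of a single comparison is possible, and its genes were counted by size at an absolute log2 difference of 1 or more. The same counts between the 3 vehicle arrays served as a background. These arrays differ in construct, and DMSO from ethanol also in vehicle and time, so this background is not a replicate error.

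One test spanned all 6 arrays. DMSO, DNMAML-ER with ethanol and Notch1-ER with OHT formed a Notch-high arm, and DAPT, DNMAML-ER with OHT and Notch1-ER with ethanol a Notch-low arm. The arms were compared with limma 3.58.1 (lmFit and eBayes with a trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with the pair as a block, which left 2 residual degrees of freedom. It asks whether the 3 perturbations move a gene together and tests none of them singly. It was tested on simulated data with 12150 genes and with the spreads of these arrays, dealt to genes at random. Each changed gene got the same change in all 3 pairs. Of 200 genes changed by 1 on the log2 scale it recovered 60.0%, and of 200 changed by 2 it recovered 92.5%, with 4 false calls each time. The 3 perturbations need not change a gene equally, so these shares do not give the recovery to be had in the real arrays.

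Sets of genes picked in 1 comparison were read in arrays that took no part in picking them. The median difference of a set was placed among 10000 random sets of the same size matched on mean level in 20 bins. This percentile describes these arrays and is not a p-value. The random sets were not matched on how widely genes varied between arrays. Genes picked for a 2-fold difference can vary more, so a set nearly even in sign can reach an extreme percentile. As a check, 0.2 was added to the measured Notch1-ER differences of 60 genes drawn at random. The set then lay at percentile 100, and at 34.0 without the shift. Genes drawn at random were not picked for a 2-fold difference, so this does not test the method on sets that were. Correlations between comparisons run across genes, which are not independent replicates, and no 2 of the 3 comparisons share an array.

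The groups, the sizes, the floor, the arms and the alternatives were chosen before the data were examined. The alternatives were a second quantile normalization, cyclic loess, no floor, a floor on the mean, another size, a fit without the pair block or without the trend, and leaving out each pair. The reading of gene sets in other arrays, the alternatives for it and for the correlations, and the cell-cycle marker genes of scran 1.30.0 were added after the data were seen.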

Results

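The series addresses how Notch1 signalling controls transcription in Beko cells, by lowering Notch activity in 2 ways and raising it in 1. DAPT blocks γ-secretase, the protease that releases the active intracellular part of Notch. DNMAML is a dominant-negative Mastermind, which occupies the Notch transcription complex without activating it. Notch1-ER carries Notch1, and both fusions hold an oestrogen receptor part that OHT switches on. Each of the 6 conditions was measured on 1 array, so the 3 treated arrays were each set against 1 vehicle array and no difference within a pair has a replicate check. The deposited log2 values cover 22414 genes, of which 12150 passed the floor. The IDs could not be paired with gene symbols, so what follows describes how many genes differed, in which direction, and which sets of genes moved with each other.

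DAPT gave the widest of the 3 treatment differences. After 24 h at 10 μM, 198 of the 12150 genes differed at least 2-fold from DMSO, 128 of them higher and 70 lower. The differences ran from -2.97 to 4.08 on the log2 scale, with a standard deviation across genes of 0.36. At a size of 1.5-fold the count was 993, of which 636 were higher and 357 lower. More genes were thus higher than lower on the DAPT array, though without the floor the share of higher genes at 2-fold was 56.5%. Vehicle arrays could differ in this way too. Against DMSO at 2-fold, the Notch1-ER ethanol array had 116 genes higher and 77 lower, and the DNMAML-ER ethanol array 122 and 120.

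Switching on DNMAML-ER with OHT for 48 h gave 96 genes that differed at least 2-fold from ethanol, 62 higher and 34 lower. The differences ran from -2.79 to 3.53 with a standard deviation across genes of 0.28. At 1.5-fold, 299 genes were higher and 165 lower. The share of higher genes at 2-fold was 64.6%, as it was for DAPT.

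Switching on Notch1-ER gave the fewest. With OHT, 64 genes differed at least 2-fold from ethanol, 46 higher and 18 lower, over a range of -2.01 to 3.28 and with a standard deviation of 0.24. At 1.5-fold, 186 genes were higher and 99 lower. Without a floor on low levels the count at 2-fold was 101, with 61 higher, so that the share of higher genes was 60.4% in place of 71.9%.

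The vehicle arrays give a background for these sizes. The 2 ethanol arrays, from lines with different fusions, differed at least 2-fold in 13 genes with a standard deviation of 0.19. The counts of 96 and 64 in the OHT pairs lay above it. Without the floor the ethanol arrays differed in 48 genes, against 140 for DNMAML-ER and 101 for Notch1-ER, and with the floor on the mean level in 6 genes, against 77 and 52. The DMSO array of the parental cells differed at least 2-fold from the DNMAML-ER ethanol array in 242 genes and from the Notch1-ER ethanol array in 193. The DAPT count of 198 lay between these counts, which come from arrays that also differ in vehicle and in time. A second untreated parental culture, which would be a closer background for DAPT, was not analysed here.

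**Figure D1:**
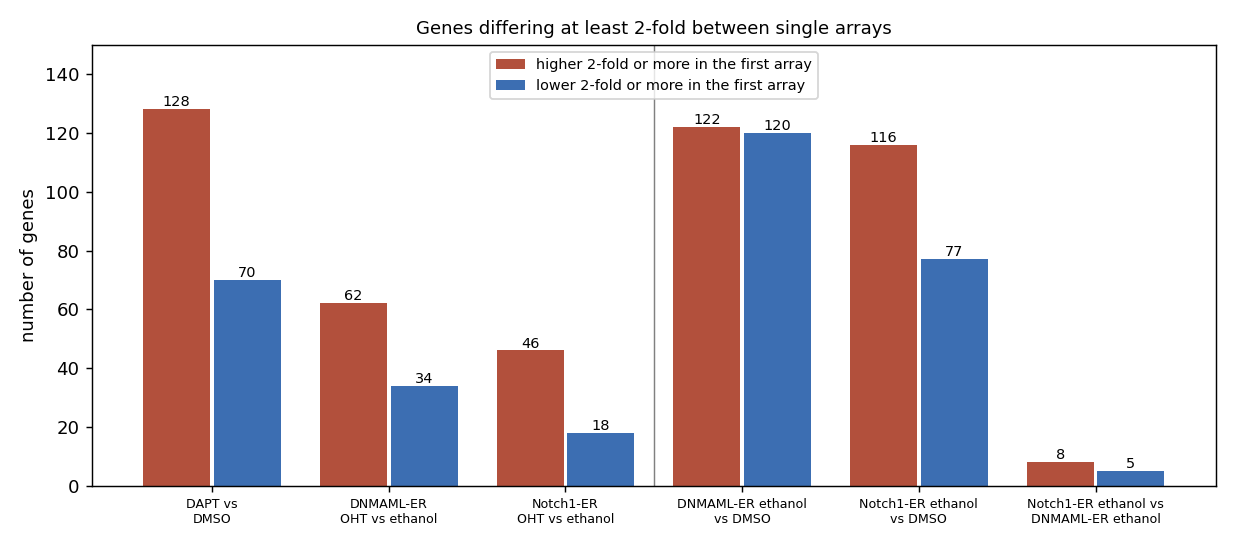
Number of genes (vertical axis) at least 2-fold higher (red) or lower (blue) in the first array named than in the second, for the 3 treated arrays against their vehicles (left of the line) and between the vehicle arrays (right of the line), 1 array per condition. The 2 ethanol arrays differed in 8 and 5 genes, against 62 and 34 for DNMAML-ER and 46 and 18 for Notch1-ER with OHT.

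Many of the genes that differed under 1 way of lowering Notch activity differed in the same direction under the other. Of the 128 genes higher 2-fold with DAPT and the 62 higher with DNMAML-ER, 34 were shared, where independent lists would share 0.653. Of the 70 and 34 lower genes, 13 were shared, where independent lists would share 0.196. In the opposing directions, 2 genes were higher with DAPT and lower with DNMAML-ER, and 0 were lower with DAPT and higher with DNMAML-ER. Across all 12150 genes the log2 differences had a Pearson r of 0.53 and a Spearman rho of 0.49. Without the floor, which adds weakly expressed genes, r was 0.37.

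The same held for genes picked in 1 inhibitor and read in the other. The 128 genes higher 2-fold with DAPT had a median DNMAML-ER difference of 0.64, and 102 of them were above 0. The 70 lower genes had a median of -0.47, and 59 were below 0. Read the other way, the 62 genes higher with DNMAML-ER had a median DAPT difference of 1.10, with 58 above 0, and the 34 lower genes had a median of -0.82, with 29 below 0. The medians for higher genes lay at percentile 100 of 10000 random sets matched on level, and those for lower genes at percentile 0, that is, beyond all random sets drawn.

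Notch1-ER did not mirror the inhibitors across the whole transcriptome. Over all 12150 genes its differences had an r of -0.03 with those of DAPT and of 0.03 with those of DNMAML-ER. Among the 64 genes that differed 2-fold with Notch1-ER, however, r was -0.40 with DAPT and -0.37 with DNMAML-ER, and 70.3% had the opposite sign under DAPT. The 46 genes higher with Notch1-ER had a median DAPT difference of -0.38 and a median DNMAML-ER difference of -0.24, both at percentile 0. The 18 lower genes had medians of 0.58 and 0.22, at percentiles 100 and 99.97. Genes that responded most to Notch1-ER therefore tended to lie on the other side under both inhibitors.

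**Figure D2:**
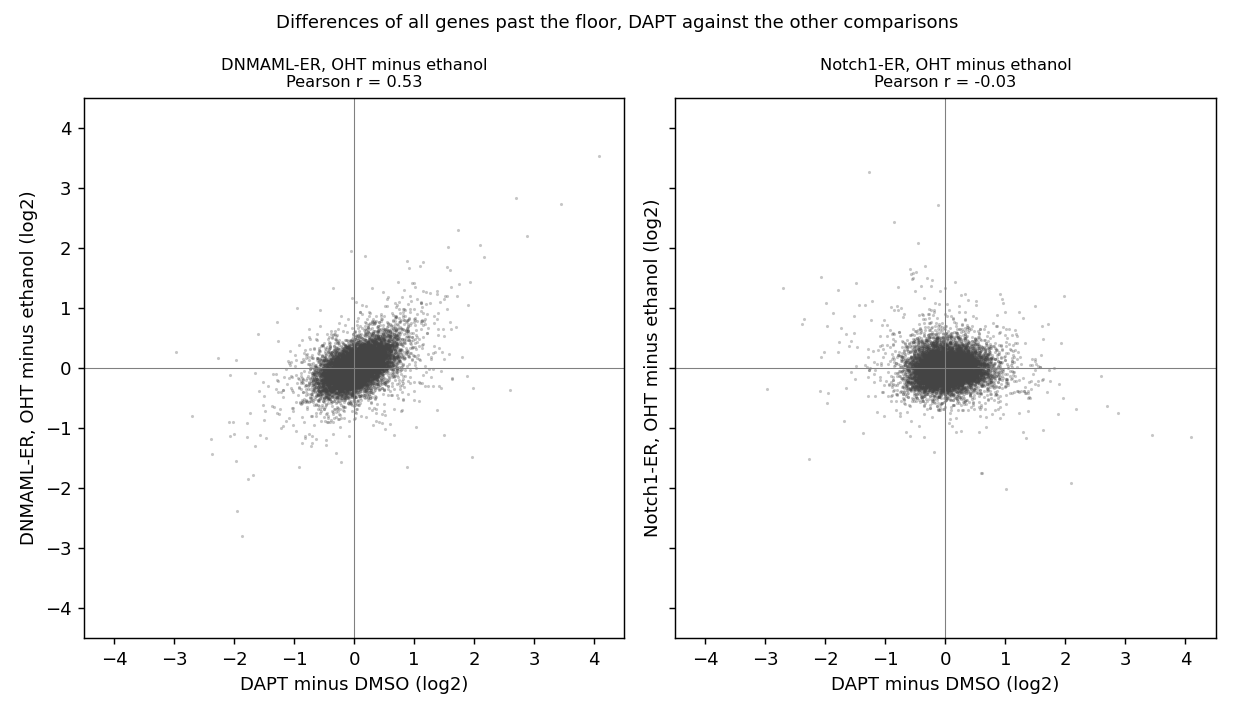
Log2 difference of each of the 12150 genes (points) in DAPT against DMSO (horizontal axes) and in the DNMAML-ER pair (left, vertical axis) or the Notch1-ER pair (right, vertical axis), 1 array per condition. The left cloud rises with r = 0.53, and the right cloud has r = -0.03.

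The genes that differed 2-fold under both inhibitors lay, by their medians, on the opposite side in the Notch1-ER pair. The 13 genes lower under both had a median Notch1-ER difference of 0.57, at percentile 100, and 10 of them were above 0. The 34 genes higher under both had a median of -0.19, at percentile 0, and 20 of them were below 0. The second set is the less certain. With cyclic loess its median was -0.07 at percentile 5.94, and with the inhibitor sets picked at 1.5-fold it was -0.04 at percentile 5.00 over 167 genes. Picked on DAPT alone, the 128 higher genes had a median Notch1-ER difference of -0.11 (percentile 0), with 56 above 0 and 72 below. The 70 lower genes had one of 0.18 (percentile 100), with 45 above 0 and 25 below. Picked on DNMAML-ER alone, the 34 lower genes had a median of 0.12 (percentile 99.96), with 19 above 0 and 15 below. The 62 higher genes had a median of 0.07 (percentile 98.7), on the same side as DNMAML-ER, with 33 above 0 and 29 below. Both DNMAML-ER sets, and the 128 genes higher with DAPT, were thus nearly even in sign despite their percentiles.

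In all 3 pairs together, 32 genes differed at least 1.5-fold in the direction the design gives. Of these, 15 were higher and 17 lower where Notch activity was higher. At this size, the other ways of assigning signs to the 3 pairs gave fewer genes. The pattern that turns the Notch1-ER pair, so that it goes with the inhibitors, gave 16, and the patterns that set the 2 inhibitors against each other gave 2 and 1. At 2-fold in every pair, 5 genes passed, 2 higher and 3 lower with Notch activity.

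The 2 genes with the largest shared difference towards higher levels with Notch activity were ENSMUSG00000048534 and ENSMUSG00000031785. ENSMUSG00000048534 was 3.47-fold lower with DAPT, 2.23-fold lower with DNMAML-ER and 2.46-fold higher with Notch1-ER. ENSMUSG00000031785 was 3.99-fold lower, 2.15-fold lower and 2.12-fold higher. The 2 with the largest shared difference towards lower levels were ENSMUSG00000095891 and ENSMUSG00000029530. ENSMUSG00000095891 had log2 levels of 4.23 with DMSO and 6.32 with DAPT, 2.88 and 4.93 with ethanol and OHT in the DNMAML-ER line, and 4.21 and 2.30 in the Notch1-ER line. Only the DAPT level exceeded the floor of 5.54, so no fold is given for this gene. ENSMUSG00000029530 had the largest positive difference of all 12150 genes under both inhibitors, 17.0-fold with DAPT and 11.6-fold with DNMAML-ER, and was 2.23-fold lower with Notch1-ER. Its log2 level was 7.12 with DMSO and 11.21 with DAPT.

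**Figure D3:**
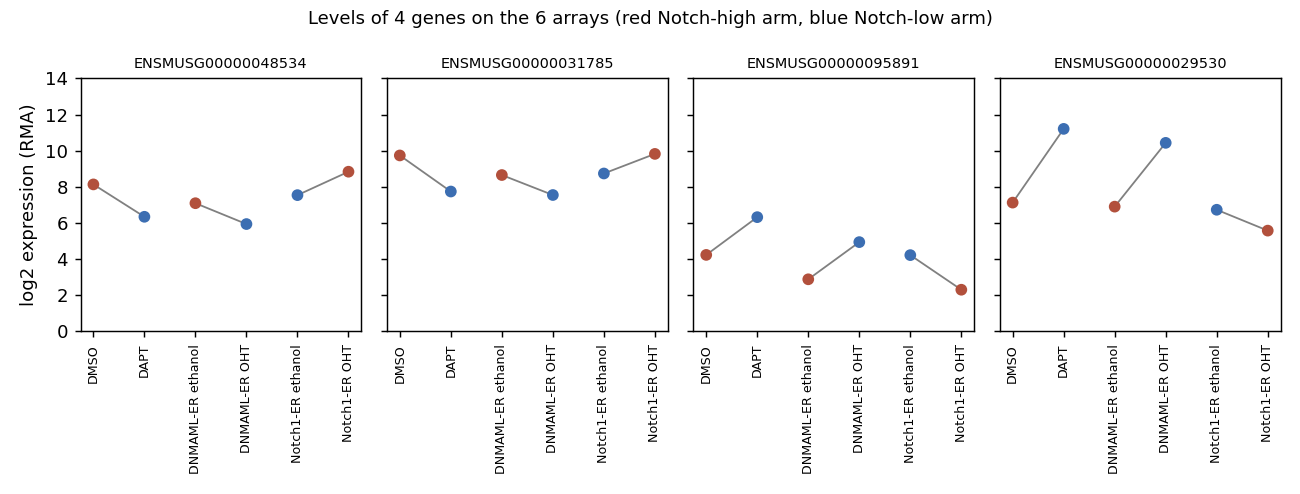
Log2 expression (vertical axis) of 4 genes on each of the 6 arrays (points, 1 array per condition), with lines joining each treated array to its vehicle, red for the Notch-high and blue for the Notch-low arm. In each panel the DAPT and DNMAML-ER lines slope one way and the Notch1-ER line the other.

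The test of a shared Notch effect over the 3 pairs called no gene. By limma with the pair as a block, 0 of the 12150 genes passed an adjusted p of 0.05. The smallest adjusted p by limma was 0.051, for ENSMUSG00000095891, whose Notch-high minus Notch-low difference was -2.02 ± 0.16 (moderated SE of the fit, 3 pairs). That gene rests on levels under the floor on 5 of the 6 arrays, and with the floor set on the mean level the smallest adjusted p by limma was 0.11. The corresponding limma values were 1.41 ± 0.14 with an adjusted p of 0.079 for ENSMUSG00000048534, 1.40 ± 0.19 with 0.20 for ENSMUSG00000031785, and -2.92 ± 0.49 with 0.21 for ENSMUSG00000029530. These SEs borrow spread from other genes and are not those of the 3 pairs alone. The SD of the 3 signed differences was 0.09 for ENSMUSG00000095891 and 1.56 for ENSMUSG00000029530. At an unadjusted p of 0.05 by limma, 1026 genes passed, 641 of them lower in the Notch-high arm. With no effect on any gene, 607.5 would be expected to pass. Of the other splits of the 6 arrays into 3 against 3, those that part all 3 pairs gave 1647, 120 and 152 genes at that p. The 1647 came from all treated against all vehicle arrays. Each remaining split parts 1 pair only. Under the block its fit measures that pair alone, so it is not comparable with the real split. A second quantile normalization of the arrays gave 2 calls, and a fit without the trend gave 1.

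The outcome of this test rested on the Notch1-ER pair. With the DAPT and DNMAML-ER pairs alone, limma called 778 genes at an adjusted p of 0.05, of which 561 were higher and 217 lower with the inhibitors, on 1 residual degree of freedom. Without the DAPT pair or without the DNMAML-ER pair it called 0. The median Notch1-ER difference was 0.02 for the 561 genes and -0.14 for the 217, neither on the side the design gives for Notch. In the DAPT and DNMAML-ER pairs the Notch-low arm is the treated arm. The fit on those pairs alone thus cannot part lower Notch activity from another response to treatment.

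OHT was given to both fusion-carrying lines, and the genes that followed it in both were few in number. At 2-fold, 2 genes were higher with OHT in both lines, where independent lists would share 0.235. None was lower in both, where independent lists would share 0.050. In opposite directions, as the design gives for Notch, 4 genes were lower with DNMAML-ER and higher with Notch1-ER, and 3 were higher with DNMAML-ER and lower with Notch1-ER. Independent lists would share 0.129 and 0.092. Genes higher with OHT in both lines thus also exceeded independent lists, so these counts do not show that a shared OHT response is absent. At 1.5-fold, 36 genes followed OHT in both lines and 45 went in opposite directions, and without the floor the counts at 2-fold were 6 and 9.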

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

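Of the tests in this part, those on OHT itself, on a shared array batch, on scatter in the Notch1-ER pair and on activity of the fusions without OHT were chosen after the results they measure had been seen in part.

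At 2-fold, 7 genes went in opposite directions with OHT in the DNMAML-ER and Notch1-ER lines, 4 lower and then higher and 3 the reverse. Each line has 1 array per condition, and the difference between the lines was not tested.

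The first pattern is that DAPT and DNMAML-ER differences went together, with r = 0.53. After cyclic loess r was 0.52, so a level-dependent bias of the kind loess removes does not account for it. Among the 4050 most highly expressed genes r was 0.64. The 2 pairs share no array, so independent scatter at low levels would only lower r, and that value tests no cause. OHT was not given to the DAPT pair and so cannot by itself produce the agreement; the 2 OHT pairs had r = 0.028 over all genes and 0.22 among the 4050. The DNMAML-ER OHT array was closer to the DAPT array (SD of differences 0.385) than the other fusion-line arrays were (0.486 to 0.504). Its SD to the DMSO array was 0.377, so it was no closer to DAPT than to DMSO. Being nearer to DAPT than the other fusion-line arrays has 2 possible sources here. A shared loss of Notch activity and an array batch of the DNMAML-ER OHT and DAPT arrays would both give it. The labels name no batch, so for the agreement across all genes these cannot be told apart. The Notch1-ER pair holds neither of those arrays. There, 10 of the 13 genes lower under both were above 0 (median 0.57, percentile 100). A batch of those 2 arrays alone gives no reason for that, but the genes are few and the random sets were not matched on spread.

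The second pattern is that Notch1-ER mirrored the inhibitors in its most responsive genes but not across all genes. Scatter hiding a mirror image does not account for it alone: r with DAPT was -0.40 among the 64 genes that differed 2-fold with Notch1-ER, but 0.13 among the 4050 most highly expressed genes, where it should have been negative. Activity of the fusions without OHT stays open, because its tests on the ethanol arrays were mixed. The 70 genes lower with DAPT were higher on the Notch1-ER than on the DNMAML-ER ethanol array, by a median of 0.21 (percentile 100), as a leak would give, but the 128 genes higher with DAPT were not lower there (median 0.03, percentile 90.5). The 46 genes higher with Notch1-ER were lower on the DNMAML-ER ethanol array than on the DMSO array, by a median of -0.14 (percentile 0.53), but the 18 lower genes were not higher there (median -0.09, percentile 8.54). On the Notch1-ER ethanol array against DMSO, which also differ in vehicle and time, both DNMAML-ER sets went as a leak would give, the 62 higher genes at -0.16 (percentile 0.01) and the 34 lower genes at 0.35 (percentile 100).

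The third pattern is the Notch1-ER response of genes that differed 2-fold under both inhibitors. The median was 0.57 for the 13 lower genes and -0.19 for the 34 higher genes, each in the direction predicted from Notch activity. For the higher genes the median was -0.11 (percentile 1.01) after a second quantile normalization and -0.07 (percentile 5.94) after cyclic loess, the latter within the range of random sets, so that part may depend on how the arrays are scaled.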

How the results depend on the processing

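Counts at 2-fold kept within 1.5 times under both other normalizations. At a size of 1.5-fold they were 993 for DAPT, 464 for DNMAML-ER, 285 for Notch1-ER, 1090 and 1088 for the DNMAML-ER and Notch1-ER ethanol arrays against DMSO, 128 between the ethanol arrays, and 36 for genes following OHT in both lines. Without the floor the count was 101 for Notch1-ER, 48 between the ethanol arrays and 6 for OHT in both lines, because more genes enter, and r between DAPT and DNMAML-ER was 0.37. With the floor on the mean, the ethanol arrays differed in 6 genes. Genes sharing the Notch direction in all 3 pairs numbered 5 at 2-fold and 45 to 228 when 1 pair was left out, which loosens the criterion. The limma count for the 3 pairs was 2 with quantile normalization (smallest adjusted p 0.048), 1 without the floor, 1 without the trend, 0 without the pair block, and 0 to 778 when 1 pair was left out, the highest without the Notch1-ER pair. The cause was not tested. Genes higher under both inhibitors had a Notch1-ER median of -0.068 with cyclic loess and -0.040 at 1.5-fold, both no longer outside the range of random sets. The 4 printed genes kept their direction under both normalizations. Averaging several probe sets of a gene was not run, since each ID has 1 probe set, and the alternatives for the gene lists were not run. No paired analysis by replicate number was possible because the labels carry none. The design has 10 splits of the 6 arrays into 3 against 3, too few for a share under 0.05: all 10 gave as many genes as the real 0, and the highest other was 0. At an unadjusted p of 0.05 the real split gave 1026 genes and the split of all treated against all vehicle arrays 1647. The other splits that part all 3 pairs gave 120 and 152. With the pair as a block, the 2 splits in which only the DAPT pair is parted are the same fit of that pair, which gave 1588.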

Other observations

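Of the tests here, the one on level-dependent normalization and the one on cell-cycle genes were written before their results were seen, on patterns or lists chosen after the data were seen.

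Cell-cycle marker genes of G1 and S with DAPT, and of G2 and M with Notch1-ER, had medians above the range of random sets. The lists are those that scran's cell-cycle classifier, trained on mouse cells, uses as leading genes of 1 phase alone. With DAPT the median differences were 0.17 for 49 genes of G1 (percentile 98.74), 0.17 for 88 genes of S (percentile 99.82) and 0.15 for 47 genes of G2 and M (percentile 97.3). With DNMAML-ER they were 0.08 (percentile 96.2), 0.04 (percentile 74.2) and 0.05 (percentile 79.4). With Notch1-ER the G2 and M list had a median of 0.05 (percentile 99.69), and G1 and S lay at percentiles 31.3 and 59.6. Between the vehicle arrays every list lay inside the range of random sets. The G2 and M medians against DMSO were nevertheless larger in size. They were 0.06 on the DNMAML-ER ethanol array (percentile 81.4) and 0.09 on the Notch1-ER ethanol array (percentile 69.6). A shared change in cell-cycle composition, proposed as a cause of the agreement between the inhibitors, needed the S list or the G2 and M list outside the range of random sets in both. Neither was with DNMAML-ER, and with DAPT the 3 phases were higher together. The criterion left out the G1 list, which was above that range with DAPT and just inside it with DNMAML-ER (percentile 96.2). A shared cell-cycle change is therefore not set aside.

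Highly expressed genes showed an agreement that the Notch design does not give. Among the 4050 most highly expressed genes, the DNMAML-ER and Notch1-ER differences had r = 0.22, although OHT should change Notch activity in opposite ways in the 2 lines, and DAPT and Notch1-ER had r = 0.13. Level-dependent normalization was the explanation tested, and after cyclic loess r between the OHT pairs was still 0.22. A hypothesis left open is a small response to treatment common to all 3 pairs that lies beneath a larger Notch response in fewer genes. The 217 genes that limma called lower over the DAPT and DNMAML-ER pairs, with a Notch1-ER median of -0.14, go in the direction of such a response, while the 561 called higher had a median of 0.02 and hardly follow it. Replicate vehicle and OHT arrays of cells without a fusion would test it for OHT, but not for a response shared with the DAPT pair, which got no OHT.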
